A study of Homo sapiens with 11 samples.

How the data were processed

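Per the labels, RNA from fresh chordoma tumours was extracted with Trizol and a bead beater, and notochord RNA came from laser-captured tissue and a small-input kit. Each RNA was amplified with the Nugen Ovation Pico kit and the exon module before Illumina library preparation. That kit does not mark strand. The control RNA was amplified with the same kit.

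The deposited values are read counts per gene in the layout of STAR's gene count output, 1 column of counts per file, with no normalization. Per the submitters' processing notes, STAR 2.7.10a and Bowtie 0.12.7 were used with the GRCh38 build, and the role of Bowtie is not given in the sources used here. The annotation release and the strand setting are also not given in the sources used here. Since no strand use is stated, reads of a gene and an overlapping or antisense partner cannot be told apart. Each file held 61598 gene IDs and 4 rows that name no gene (unmapped, multi-mapped, outside genes, ambiguous). Those 4 rows stayed out of library sizes and tests, and the genes held 40.7% of reads in chordoma 3 and 9.79% in chordoma 11, the highest and lowest shares of the libraries. Reads that map to several places are in those rows, so genes with near-identical copies are undercounted.

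Gene symbols were matched on IDs without version, and 61588 of the IDs had one. Coordinates and gene types came from GENCODE release 29 on GRCh38, in which 58396 of the IDs were found, 35849 of them with the same version. XIST, TSIX and Y-linked genes, 558 IDs, were left out of the tests.

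Depth was 1902554 to 5165357 gene counts per library, so 3 counts correspond to between 0.581 and 1.58 CPM before TMM scaling. After TMM scaling over 9 libraries, 1 count was 1.01 CPM in chordoma 10 and 0.870 CPM in notochord 1. Low CPM values in these libraries therefore rest on few reads. Amplified reads without molecular identifiers are not independent molecules, and floors cover counting error only.

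Groups were taken from the labels, with 6 chordoma, 3 notochord and 2 control libraries. The comparison of chordoma with notochord used edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors, the quasi-likelihood F test with a robust prior and Benjamini-Hochberg adjustment at 0.05. The control libraries were left out of that fit. Each tissue was compared with the controls in a fit of its own. The design took the 2 controls for libraries of one RNA. Their contents differ, the fits were kept as designed, and the large spread between them enters those tests. CPM values of genes, as means or for single libraries, are TMM-scaled and are not shares of a library's counts. Scaling was over 9 libraries for chordoma against notochord and over all 11 for comparisons with the controls. SE is the log2 difference divided by the square root of the F statistic.

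A set of 46 gene lists (785 entries, 784 matched) covering cell types, tissues and pathways was fixed before the data were examined. Lists with at least 3 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with the preset correlation of 0.01, and 3 lists were too small. Camera with an estimated correlation and fry were run beside it. The rule for named genes was also fixed before the data were examined. It took TBXT, KRT8, KRT18, KRT19, CD24 and SOX9, and the 10 largest increases and 10 largest decreases among genes past the threshold without overlap between the groups and with a mean log2 CPM of at least 3. It also took up to 4 members past the threshold of each list described, or the 2 most abundant where none passed. Some genes that the rule takes are not reported here. For the controls it took the extremes under the same conditions and TBXT. Shares of reads were compared by a two-sided exact permutation test over the 84 splits.

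Alternatives were other size factors (RLE, upper quartile), filters (none, or a CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, limma voom with quality weights, a non-robust prior, all libraries in one fit, subsets of genes, a replicate block and each library left out. Fits without the libraries rich in mitochondrial reads or in reads outside genes, with chordoma 3 and 4 summed, or with the share of reads outside genes as a covariate were chosen after seeing the data. DESeq2 was run on every gene with any count, without filterByExpr (47710 genes for chordoma against notochord). Its counts therefore differ from those of edgeR in both tool and gene set. Count code was tested on simulated data with 200 changed genes. At the spread of the chordoma and notochord libraries (13546 genes tested) it recovered 1.49% of genes changed 4-fold, 62.1% of those changed 16-fold and 92.4% of those changed 64-fold, none in the wrong direction. For notochord against the controls (14504 genes tested) it recovered 21.2% of genes changed 64-fold, and for chordoma against the controls (15915 genes tested) 65.2%.

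Chordoma 3 and 4 were the most alike pair, with a correlation of log2 CPM across genes of 0.956, against 0.905 for notochord 2 and 3. Whether they come from separate tumours is not given in the labels, and the counts cannot show it. They were kept as 2 libraries as labelled, with a fit that sums them as an alternative.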

Results

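Gene expression was measured by RNA sequencing in 11 libraries. Chordoma, a tumour of the axial skeleton thought to arise from remnants of the notochord, was represented by 6 libraries from fresh resected tumours. Notochord, the embryonic rod that patterns the spine, was represented by 3 libraries from laser-captured tissue. Commercial control RNA amplified with the same kit gave 2 further libraries, which share a label but differed in content. Gene counts in chordoma 1, 3, 4, 10, 11 and 98 were 4295873, 3565680, 3708874, 4628813, 1902554 and 2771231. They were 3151873, 3335264 and 4141185 in notochord 1, 2 and 3, and 3968075 and 5165357 in control 1 and 2. All reads per library numbered 8759107 to 19428013. The labels tie no library to a donor, so the p-values measure the spread between these libraries, and they are too small if captured areas shared a donor. Tumour and notochord also differed in how RNA was obtained, so tissue and collection method cannot be separated in any comparison of these groups. Since the notochord is an embryonic structure, developmental stage may differ between the groups as well, and it was not tested.

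The share of reads falling in genes differed widely within each tissue. Reads outside genes made up 72.8% of all reads in chordoma 11 and 60.3% in chordoma 98, against 19.9% in chordoma 4 and 28.7% in chordoma 1. In notochord they made up 13.1%, 52.7% and 52.0% in libraries 1, 2 and 3, and in the controls 35.6% and 30.4%. Mitochondrial genes took 82.6% of gene counts in chordoma 10 and 63.6% in notochord 1, and between 11.0% and 30.8% in the other libraries, controls included. For none of the 6 measures of read assignment did a difference between the tissues pass a two-sided exact permutation test (adjusted p = 1.0 for each, where the smallest p the 84 splits allow is 0.0119). The unadjusted p for reads outside genes was 0.964 by the exact permutation test, with means of 37.9% ± 22.8 (SD, n = 6) in chordoma and 39.3% ± 22.7 (SD, n = 3) in notochord.

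**Figure D1:**
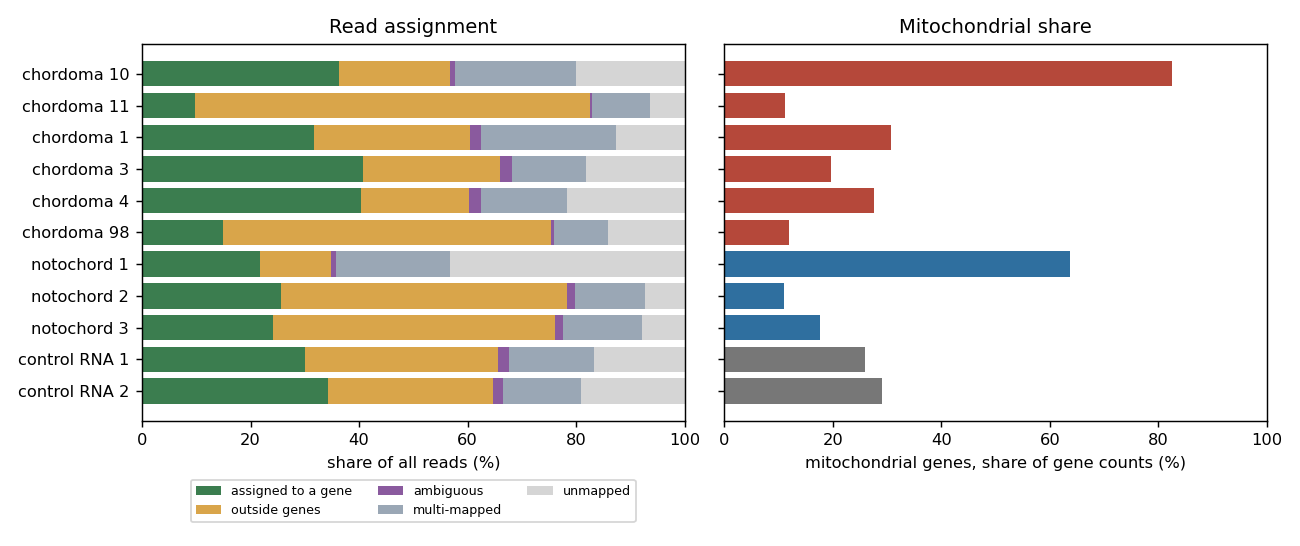
Left, share of all reads by assignment (%) for each of the 11 libraries; right, mitochondrial genes as a share of gene counts (%), coloured by group. Reads outside genes reach 72.8% in chordoma 11, and the mitochondrial share reaches 82.6% in chordoma 10 and 63.6% in notochord 1.

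The first comparison asked how chordoma differs from notochord, and whether the genes that mark both tissues keep their level in the tumour. TBXT, the transcription factor brachyury that specifies the notochord (GRCh38 chromosome 6, 166157656 to 166168700), was read in every chordoma and notochord library. Its mean was 165 ± 92.2 CPM (SD, n = 6) in chordoma and 178 ± 39.6 CPM (SD, n = 3) in notochord, a log2 difference of -0.11 ± 0.68 (SE, edgeR adjusted p = 0.966). SOX9, a regulator of chondrogenic and notochordal cells, was at 308 ± 197 CPM in chordoma and 217 ± 106 CPM in notochord (log2 difference 0.51 ± 0.73, edgeR adjusted p = 0.791). CD24, a surface glycoprotein of the nucleus pulposus, was at 162 ± 24.8 CPM against 42.4 ± 9.45 CPM. Every chordoma library lay above every notochord library for CD24, but the difference did not pass the threshold (edgeR adjusted p = 0.162). The keratins KRT8, KRT18 and KRT19 differed by 1.15, 2.29 and -2.06 on the log2 scale, and none passed (edgeR adjusted p = 0.636, 0.317 and 0.464). KRT19 reached 4570 CPM in notochord 1 and 61.1 and 56.1 CPM in the other 2 notochord libraries, and without notochord 1, chordoma 11 and chordoma 98 its difference was 3.20. Keratin genes have near-identical pseudogene copies, and KRT8 and KRT18 overlap in the annotation, so their counts are uncertain. Across the list of notochord and chordoma markers, 0 of 19 measured members passed by edgeR, and 0 did adjusted over the list alone. The median log2 difference was 0.01 (camera adjusted p = 0.827, and 0.915 with an estimated correlation). Members moved both ways, 10 up and 9 down. Named after their values were seen, S100B was at -3.04 with every chordoma below, and LGALS3 at 2.01 with every chordoma above. Neither passed (edgeR adjusted p = 0.176 and 0.241). In simulated data only 1.49% of 4-fold changes were recovered, so an unchanged level is not shown.

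Of 15220 genes tested, 15 were higher and 101 lower in chordoma than in notochord at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and 109 of these 116 genes were protein-coding. The groups did not overlap in 1240 of the genes tested, where chance gives 1.19% per direction, and in 111 of the 116, which were selected for a difference. Log2 differences ran from 3.35 to 8.40 among genes that were higher and from -9.34 to -2.80 among those that were lower.

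Genes of the cartilage matrix were lower in chordoma. Of 20 measured members of the cartilage list, 11 fell and 9 did not pass, and 14 were lower and 1 higher adjusted over the list alone. The 1 higher was PRG4, lubricin of joint surfaces, at 8.91 against 0.385 CPM (edgeR adjusted p = 0.131 over all genes), named after its values were seen. MATN1, the cartilage matrix protein matrilin 1 (chromosome 1, 30711277 to 30723587), was at 5.39 ± 5.26 CPM (SD, n = 6) in chordoma and 359 ± 66.6 CPM (SD, n = 3) in notochord, a log2 difference of -6.07 ± 0.82 (SE, edgeR adjusted p = 0.0184). HAPLN1, which links aggrecan to hyaluronan, was at 3.56 ± 2.96 against 170 ± 117 CPM. COL9A1, a chain of type IX collagen, was at 2.10 ± 2.96 against 209 ± 92.6 CPM. COL11A2, a chain of type XI collagen, was at 5.54 ± 6.57 against 891 ± 987 CPM, with 2028, 258 and 387 CPM in notochord 1, 2 and 3. COL9A2, another type IX chain, showed the largest drop (log2 difference -9.34 ± 1.67), and its notochord mean of 1524 CPM rested on 4400 CPM in notochord 1, against 36.6 and 135 CPM in the others. The 2 most abundant members, ACAN (aggrecan) and COL2A1 (type II collagen), did not pass, and are named after their values were seen. ACAN was at 704 ± 781 against 1410 ± 1337 CPM (edgeR adjusted p = 0.659). COL2A1 was at 1196 ± 1216 against 3522 ± 2278 CPM (log2 difference -1.56 ± 0.92, edgeR adjusted p = 0.446). Over the cartilage list the median log2 difference was -4.47 (camera adjusted p = 7.3e-21, and adjusted p = 0.0503 with an estimated correlation). Neighbouring cartilage in the captured areas cannot be told apart from a lower expression in chordoma cells than in notochord cells, which was not tested.

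Skeletal muscle genes were lower in chordoma as well. Of 13 measured members, 6 fell and 7 did not pass, with 11 lower adjusted over the list alone. MYH3, the embryonic myosin heavy chain (chromosome 17, 10628526 to 10657309), was at 4.94 ± 4.74 CPM in chordoma and 432 ± 486 CPM in notochord (log2 difference -6.48 ± 1.01, edgeR adjusted p = 0.0184). TNNI2 and TNNC2, subunits of fast-muscle troponin, and MYL1, a fast-muscle myosin light chain, fell by 7.17, 5.46 and 5.67 on the log2 scale. MYH3 was 244, 985 and 68.5 CPM in notochord 1, 2 and 3, against at most 13.4 CPM in any chordoma library, and TNNI2 was 632, 151 and 13.9 CPM in notochord 1, 2 and 3. The median of the muscle list was -5.12 (camera adjusted p = 1.6e-13, and adjusted p = 0.0669 with an estimated correlation).

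Of 10 measured genes of osteoblasts and osteocytes, 4 fell and 6 did not pass, with 8 lower adjusted over the list alone. IBSP, bone sialoprotein, was at 5.37 ± 8.73 CPM in chordoma and 799 ± 531 CPM in notochord (log2 difference -7.19 ± 1.51, edgeR adjusted p = 0.0489). DMP1, an osteocyte matrix protein, was at 3.68 ± 4.07 against 153 ± 58.4 CPM, and IFITM5 and PHEX also fell. The median of the bone list was -3.83 (camera adjusted p = 9.5e-12, and adjusted p = 0.0503 with an estimated correlation). Single members of blood and marrow lists fell too, 1 of 11 erythroid and 1 of 7 neutrophil genes, and 1 of each list was lower adjusted over the list alone. HBG2, a fetal globin chain with a near-identical copy, was at 0.169 ± 0.413 against 11.3 ± 9.56 CPM. The more abundant adult globins, named after their values were seen, had higher means in chordoma and did not pass. HBB was at 492 ± 1060 against 9.59 ± 12.1 CPM (edgeR adjusted p = 0.24). HBA1 was at 171 ± 312 against 27.4 ± 20.2 CPM and HBA2 at 155 ± 280 against 66.0 ± 69.2 CPM. The chordoma SDs exceeded the means, so these means do not describe the chordoma libraries as a group. MPO of neutrophil precursors was at 3.08 ± 3.85 against 269 ± 233 CPM, and its groups overlapped because notochord 1 was below 1 CPM. The erythroid list had a median of -1.20 over 11 members (camera adjusted p = 0.00733, and adjusted p = 0.277 with an estimated correlation). The neutrophil list did not pass (camera adjusted p = 0.201, and adjusted p = 0.659 with an estimated correlation).

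Genes expressed in fetal growth and imprinted genes were lower in chordoma. Of 13 measured members, 4 fell and 9 did not pass, with 9 lower adjusted over the list alone. MEG3, a maternally expressed long non-coding RNA (chromosome 14, 100779410 to 100861031), was at 73.3 ± 94.1 CPM in chordoma and 2391 ± 715 CPM in notochord (log2 difference -5.04 ± 1.00, edgeR adjusted p = 0.046). H19 was at 2.39 ± 2.27 against 55.5 ± 35.3 CPM, IGF2 at 8.13 ± 12.2 against 208 ± 133 CPM, and DLK1 at 2.12 ± 3.81 against 209 ± 307 CPM. The DLK1 mean rested on 563 CPM in notochord 1, against 40.7 and 22.7 CPM in the others. The median of this list was -3.53 (camera adjusted p = 5.4e-13, and adjusted p = 0.0669 with an estimated correlation).

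Of 24 measured cell cycle genes, AURKB, MKI67 and TPX2 fell and 21 did not pass, with 8 lower adjusted over the list alone. MKI67, the proliferation antigen Ki-67, was at 12.9 ± 9.42 CPM in chordoma and 272 ± 204 CPM in notochord (log2 difference -4.40 ± 0.95, edgeR adjusted p = 0.0489). In notochord 1, 2 and 3 MKI67 was at 37.4, 375 and 405 CPM, while AURKB ran the other way at 73.0, 14.04 and 13.4 CPM and TPX2 at 66.1, 34.2 and 30.8 CPM. Some blood and marrow markers were low in notochord 1 like MKI67. MPO was at 0.870, 394 and 413 CPM, SPI1 at 5.22, 177 and 208 CPM, and ITGB3 at 3.48, 94.98 and 216 CPM. Others were highest there, HBG2 at 21.7, 2.96 and 9.24 CPM and ITGA2B at 25.2, 21.8 and 14.6 CPM. The median log2 CPM of the platelet list was 1.99, 1.51 and 2.07 in notochord 1, 2 and 3, and that of the erythroid list 1.99, 2.14 and 3.44. The median log2 CPM of the cell cycle list was 3.76, 3.81 and 3.30 in notochord 1, 2 and 3, against at most 2.71 in any chordoma. The median of the cell cycle list was -1.73 (camera adjusted p = 6.8e-11, and adjusted p = 0.0669 with an estimated correlation). Of 21 measured fibroblast and stroma genes, COL1A2 and COL6A2 fell and 19 did not pass, with 8 lower adjusted over the list alone. COL1A2, a chain of type I collagen, was at 90.8 ± 111 against 6284 ± 8232 CPM (log2 difference -6.12 ± 1.19, edgeR adjusted p = 0.0436). It was at 15789 CPM in notochord 1 and 1687 and 1378 CPM in the others, and COL6A2 at 212 CPM in notochord 1 and 25.4 and 17.6 CPM in the others. The median of the stroma list was -1.62 (camera adjusted p = 6.9e-07, and adjusted p = 0.1 with an estimated correlation). Single members of other lists also fell, namely the growth factor receptor FGFR3, the sclerotome transcription factor PAX1, the pseudoreceptor BAMBI of the BMP pathway and the hypoxia-inducible carbonic anhydrase CA9. FGFR3 was 348 CPM in notochord 1 and 11.7 and 13.4 CPM in the others, and CA9 was 239 CPM in notochord 1 and 8.11 and 6.25 CPM in the others. Notochord 1, which also carried the means of COL9A2, KRT19, DLK1 and COL1A2, had a median log2 CPM of hepatocyte genes of 5.46, against at most 2.03 in the other tissue libraries and 6.53 in control 1, while APOB was at 2.42 CPM there and 1147 CPM in control 1. CAPN6, a calpain-family protein, was also among the 10 largest decreases, at 821, 131 and 107 CPM in notochord 1, 2 and 3, and PAX1 was at 79.1, 10.9 and 14.6 CPM there.

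Among genes higher in chordoma, 9 met the rule for naming. GPNMB, a transmembrane glycoprotein of macrophages, osteoclasts and several tumours (chromosome 7, 23235967 to 23275108), was at 1053 ± 928 CPM (SD, n = 6) in chordoma and 12.04 ± 9.92 CPM (SD, n = 3) in notochord, a log2 difference of 6.42 ± 1.37 (SE, edgeR adjusted p = 0.0489). JUNB, an immediate early transcription factor, was at 68.4 ± 57.6 against 1.24 ± 0.347 CPM. HERC5, an interferon-induced ligase of the ISG15 system, was at 49.9 ± 28.9 against 2.36 ± 1.33 CPM. GIPC2, a PDZ-domain protein, was at 31.0 ± 9.89 against 0.766 ± 0.981 CPM. PDK4, a kinase that restrains pyruvate dehydrogenase, was at 32.6 ± 17.9 against 1.90 ± 1.24 CPM. RIPK4, a kinase of epithelial differentiation, was at 46.0 ± 33.0 against 1.76 ± 1.71 CPM. SLC46A3, a lysosomal transporter, TMEM132D and STXBP6 differed by 4.52, 3.61 and 3.35 on the log2 scale. The naming rule required all 6 chordoma libraries to lie above every notochord library, so this is no separate result for the 9. In notochord 1, GIPC2, RIPK4 and SLC46A3 had 0 counts, and JUNB, HERC5 and PDK4 had 1. TMEM132D and STXBP6 had 3 counts there and GPNMB had 5.

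**Figure D2:**
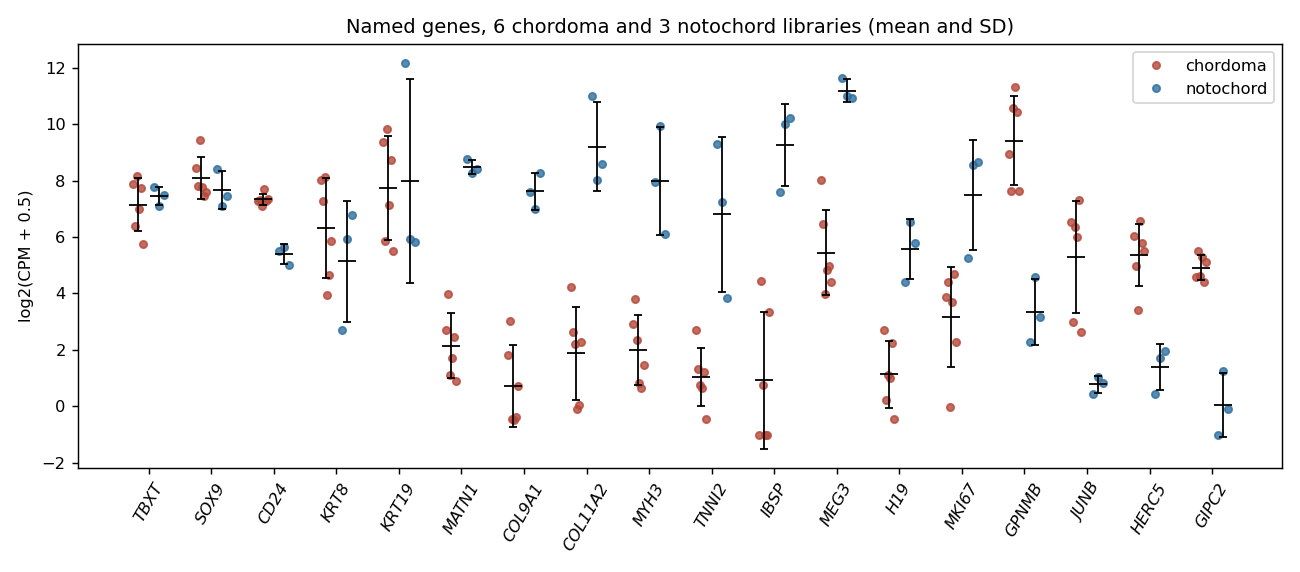
Log2(CPM + 0.5) of named genes in the 6 chordoma (red) and 3 notochord (blue) libraries, 1 point per library; black marks and bars are the mean and SD. TBXT overlaps between the groups, MATN1, COL9A1 and MEG3 lie lower in every chordoma library, and GPNMB, JUNB, HERC5 and GIPC2 lie higher.

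Interferon, T and NK cell, macrophage, MHC and immediate early lists were higher in chordoma, while B and plasma cell and neutrophil genes had medians of -2.80 and -2.32 (camera adjusted p = 0.000759 and 0.201, and adjusted p = 0.161 and 0.659 with an estimated correlation). Of 19 measured interferon-stimulated genes 0 passed over all genes, and 16 were higher adjusted over the list alone. OAS1, an antiviral enzyme that senses double-stranded RNA, was at 72.9 ± 31.6 against 20.96 ± 18.3 CPM (edgeR adjusted p = 0.272). The median of this list was 3.23, unaltered with the 2 members that were at 0 in notochord set to their bound (camera adjusted p = 2.8e-08, and adjusted p = 0.267 with an estimated correlation). Of 11 T and NK cell genes 0 passed, and 7 were higher adjusted over the list alone. Their median was 4.34, also with the 1 member at 0 in notochord set to its bound (camera adjusted p = 0.000157, and adjusted p = 0.345 with an estimated correlation). Of 17 macrophage genes 0 passed, and 8 were higher and 1 lower adjusted over the list alone. TYROBP was at 113 against 30.8 CPM and SPI1 at 28.4 against 130 CPM. The macrophage median was 2.38 (camera adjusted p = 0.000304, and adjusted p = 0.382 with an estimated correlation). Of 13 MHC class I genes 0 passed, and 4 were higher adjusted over the list alone. Their median was 1.99 (camera adjusted p = 3.1e-05, and adjusted p = 0.277 with an estimated correlation). B2M was at 2028 ± 2735 against 51.4 ± 32.6 CPM (edgeR adjusted p = 0.139). Of 11 MHC class II genes 0 passed, and 3 were higher adjusted over the list alone. Their median was 2.57 (camera adjusted p = 0.00071, and adjusted p = 0.356 with an estimated correlation). CD74 was at 345 against 37.7 CPM, with overlap between the groups (edgeR adjusted p = 0.272). Of 18 immediate early genes JUNB rose and 17 did not pass, and 5 were higher adjusted over the list alone. The immediate early median was 2.21 (camera adjusted p = 1.5e-05, and adjusted p = 0.267 with an estimated correlation). Chordoma 3 and 4 had the highest medians of the interferon, T and NK cell, macrophage and MHC lists, at 5.86 and 6.05 for T and NK cell genes (median log2 CPM) against 0.29 to 2.48 in the other 4 chordomas and -0.98 to 1.05 in notochord. For the T and NK cell, macrophage and both MHC lists the ranges of the other 4 chordomas and of notochord overlapped, and for the interferon list they did not (2.47 to 4.41 against 1.17 to 1.79).

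By camera with its preset correlation, 25 of 43 lists differed, 9 higher and 16 lower in chordoma. With the correlation estimated per list, 0 passed, and the smallest adjusted p was 0.0503. By fry, which tests whether a list's genes moved on balance one way, 12 lists passed and all 12 were lower in chordoma. The other lists that passed camera were B and plasma cell, endothelial, hedgehog, cholesterol synthesis, osteoclast, platelet, receptor tyrosine kinase, sclerotome and Wnt genes, lower in chordoma, and checkpoint, lysosome and heat shock genes, higher in chordoma. Their estimated-correlation adjusted p ran from 0.161 to 0.382. For the Wnt list the median was 0.11 and the mean -0.60, with the test pointing lower. The 18 remaining lists, among them ribosomal proteins, glycolysis and matrix proteases, had camera adjusted p between 0.0704 and 0.958.

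**Figure D3:**
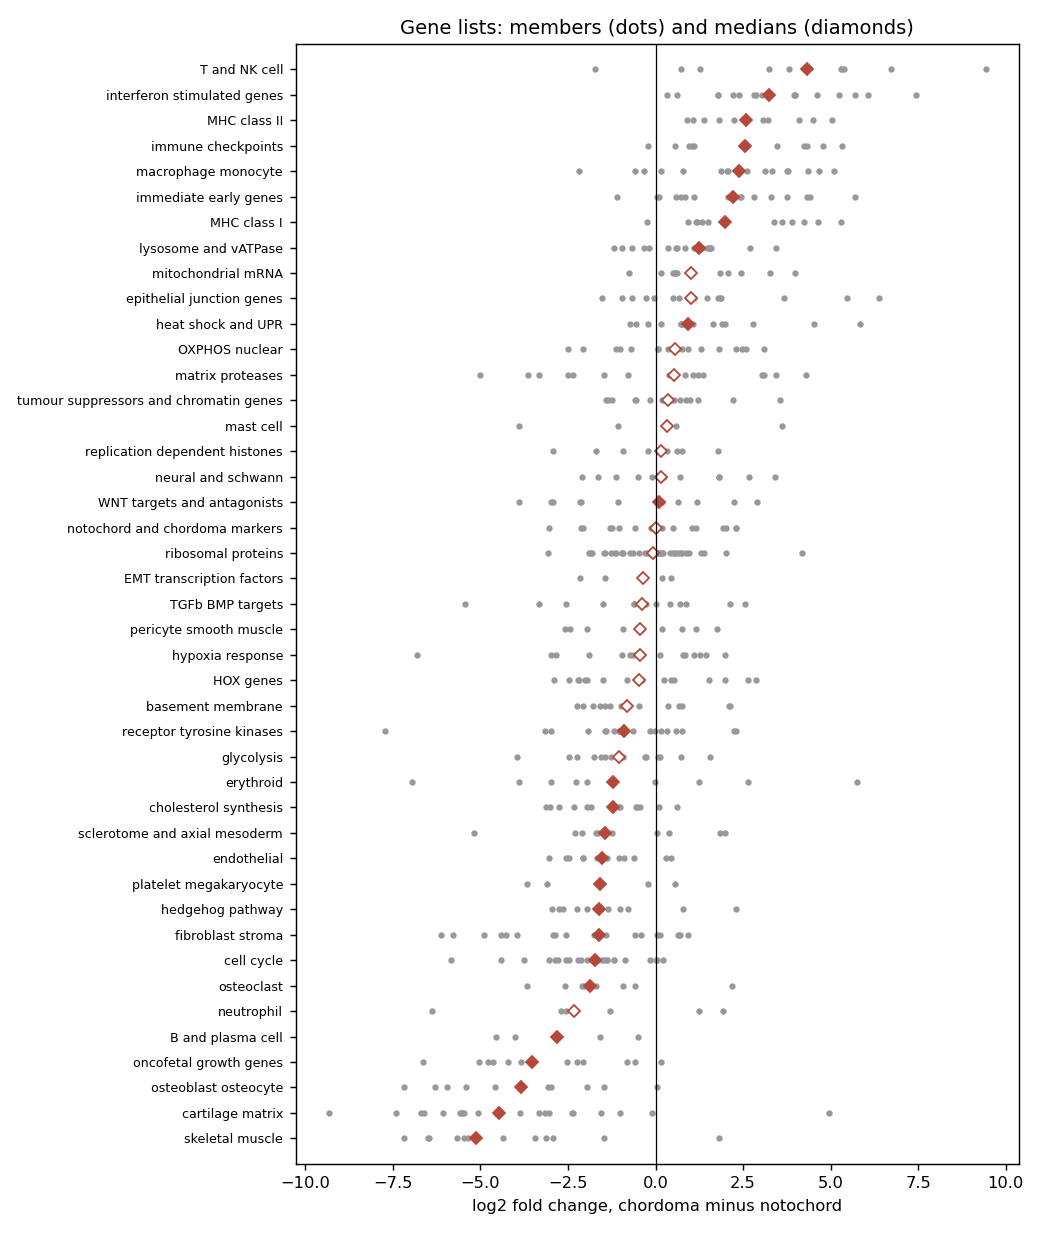
Log2 difference, chordoma minus notochord, of the measured members (grey dots) and the median (diamonds) of each of 43 gene lists; filled diamonds mark a camera adjusted p under 0.05 with the preset correlation. Cartilage, muscle, osteoblast and fetal growth lists have medians between -5.12 and -3.53, and the T and NK cell list the highest, 4.34.

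The counts depended on single libraries. Without chordoma 3, 0 genes passed in either direction, against 0 higher and 1 lower without chordoma 1, and 0 higher and 2 lower without notochord 1. They were 0 and 24 without chordoma 4, 4 and 27 without chordoma 98, 0 and 32 without chordoma 10, 0 and 73 without notochord 3, 2 and 85 without notochord 2, and 22 and 102 without chordoma 11. Without chordoma 10 and notochord 1, and also with chordoma 3 and 4 summed as 1 library, 0 passed in either direction, both tried after the data were seen. With the shared replicate numbers as a block, 21 were higher and 63 lower, and 42 of the 116 genes stayed past the threshold. At an unadjusted p under 0.05 the fit gave 1187 higher and 1171 lower. DESeq2, run on 47710 genes without the edgeR filter, called 437 higher and 342 lower. In each of 26 alternative fits every one of the 116 genes that was tested kept its direction. These genes were selected for a difference in the same libraries, 111 of them without overlap, so a kept direction carries little information.

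The comparisons with the control RNA asked which transcripts mark each tissue against an unrelated RNA. The 2 control libraries differed in content, although the labels give them one name. GFAP was at 1.21 CPM in control 1 and 1945 CPM in control 2, MBP at 15.1 and 2437 CPM, and APOB at 1147 and 1.14 CPM. These genes were chosen after their values were seen. By edgeR, 0 of 17894 genes were higher and 0 lower in chordoma than in the controls, with 1063 and 1192 at an unadjusted p under 0.05. DESeq2, run on a larger set of genes without the edgeR filter, gave 493 and 299. Likewise 0 of 15997 genes were higher and 0 lower in notochord by edgeR, with 1093 and 898 at an unadjusted p under 0.05. DESeq2, again without the filter, gave 524 and 385. Leaving out chordoma 11 gave 25 higher and 157 lower in chordoma, leaving out control 1 gave 5 and 256, and leaving out control 2 gave 0 and 7. With 0 genes in each list by edgeR, the overlap of genes higher in both tissues is 0 by construction and carries no information.

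TBXT had 0 counts in both control libraries. Normalised over all 11 libraries, it was at 179 ± 98.6 CPM in chordoma and 187 ± 27.7 CPM in notochord. Against a floor of 3 counts over the control group, 0.235 CPM, chordoma was at least 759-fold and notochord at least 794-fold higher, counting error only. The edgeR adjusted p for TBXT was 0.0566 for chordoma and 0.32 for notochord, both short of the threshold. ACAN was at 754 ± 839 CPM in chordoma, 1395 ± 1174 CPM in notochord and 0.239 ± 0.124 CPM (SD, n = 2) in the controls (edgeR adjusted p = 0.0632 and 0.32), and was named after its values were seen.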

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

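The tests on the muscle and bone lists, on genomic DNA in chordoma 11 and on the control libraries were chosen after their results were seen.

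The real grouping gave 15 genes higher and 101 lower in chordoma. Of the 84 splits of the 9 libraries into 6 and 3, 1 gave as many genes higher and 1 as many lower, the real one in each case, and the highest counts among the other splits were 0 and 5. Chance can be excluded for both counts at 5% only if the 9 libraries are independent. Chordoma 3 and 4 correlated at 0.956 across genes and notochord 2 and 3 at 0.905, a shared tumour or donor stays open, and with chordoma 3 and 4 summed 0 genes were higher and 0 lower by edgeR. For the 25 gene lists, again 1 split gave as many, but the highest of the other splits gave 24, and 16 of the others gave 20 or more. The 2 splits giving 24 set apart chordoma 1, 4 and 98 in one case, and chordoma 10 with notochord 1 and 2 in the other. The count of splits excludes chance at 5% under the same condition, but the real split lay only 1 list above the highest other. Leaving out single libraries gave 21 to 29 lists, and with an estimated correlation 0 lists passed, so the number of lists is weak evidence.

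In the 6 chordoma libraries, 110 sets of values were searched for 1 library far from the rest, and 7 had one. Chance flags about 1 in 20 such sets. In chordoma 10 the mitochondrial share was 82.6% of gene counts, with the next library at 30.8%, and the 10 most abundant genes took 78.6%, with the next library at 40.9%. In chordoma 98, LYST was at 12.35 on the log2 CPM scale with the next library at 9.87, BAMBI at 1.35 with the next at -0.38, and LIPE at 2.83 with the next at 0.23. In chordoma 11, HPGDS was at 1.95 with the next library at 5.38. In chordoma 10, HBG2 was at 0.60 with the next library at -0.98, the value of 0 counts. That HBG2 value was 1 count, and the ties at 0 fixed the outcome, so it shows no outlying library. BAMBI rested on 9 counts in chordoma 98 against 1 in the next library. The rate of 1 in 20 does not hold for such tied values.

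Muscle and bone genes stood higher in the captured notochord than in the tumours. The mean was higher in notochord for 92.3% of the measured muscle genes and 90.0% of the measured osteoblast and osteocyte genes, which restates the pattern and supports no source. The most abundant muscle genes in notochord were TTN and NEB. TTN was at 3034 ± 4506 CPM (SD) in notochord against 148 ± 199 CPM in chordoma. NEB was at 633 ± 929 against 18.2 ± 21.4 CPM. MB went the other way with 11.7 ± 10.1 against 41.0 ± 59.3 CPM. For TTN, NEB and MB the groups overlapped and none passed (edgeR adjusted p = 0.148, 0.0518 and 0.651). Notochord 1 as the whole source is argued against, since without it the list medians were -5.44 (quartiles -5.72 and -2.90) for muscle and -2.89 (quartiles -5.16 and -2.13) for bone. Neighbouring muscle or bone in the captured areas cannot be told apart from a lower expression in chordoma cells than in notochord cells, which was not tested, as tissue and collection method coincide.

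Chordoma 11 and 98 had the highest shares of reads outside genes. If these came from genomic DNA, olfactory receptor genes would be read at the density of reads outside genes, and the ratio was 1.32 in chordoma 11, above the 0.171 to 0.727 of the 9 libraries other than chordoma 11 and 98, so genomic DNA may contribute there. In chordoma 98 the ratio was 0.439, within that range, while 63.5% of the olfactory receptor genes were read there against 11.0% to 50.9% in the same 9 libraries, so genomic DNA cannot be told apart from other sources. For unspliced RNA, non-coding genes inside expressed coding genes would be read more densely than those inside silent ones, and the ratio was 3.74 in chordoma 11 and 7.59 in chordoma 98. Expressed and silent genes were defined in chordoma 1, 3, 4 and 10. The 9 libraries other than chordoma 11 and 98 gave 2.94 to 9.41, the highest in notochord 1, where 13.1% of reads lay outside genes. Libraries with low shares thus also met the bounds set beforehand for both tests. A value above all 9 was then required after the results were seen. As the 9 include notochord 2 and 3, with 52.7% and 52.0% of reads outside genes, this requirement can miss unspliced RNA, which stays open.

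The 2 control libraries differed in the genes of whole tissues. The neural list lay 5.99 higher in control 2 than in control 1 (median log2 difference). The cell cycle list differed by -4.47 and the hepatocyte list by -5.84. All of these lay outside the range of 10000 matched random lists. Amplification noise of a single RNA is argued against, since it would leave such lists near the random ones. Distinct RNAs under one label remain a candidate explanation, and a mislabelled library was not tested separately. No biological explanation was tested, as the labels give no difference between these libraries.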

How the results depend on the processing

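Fits that left out or summed more than 1 library, and the covariate fit, were chosen after seeing the data. The cause of a changed count was not tested unless stated. Of the 39 named genes past the threshold, 1011 results under the alternatives kept their direction in every case and 575 stayed past the threshold. Of the other named genes, 26 changed sign in at least 1 alternative, and 91 of their 1681 results passed the threshold. The sign and the call changed for KRT19, 3.20 without chordoma 11 and 98 and notochord 1, and for SERPINA1, 2.79 by voom with quality weights. The 25 lists kept their direction in all 475 results and stayed past the threshold in 404. The called genes and lists were selected for a difference in the same libraries, so their kept direction carries little information.

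Against 15 genes higher and 101 lower in chordoma than in notochord, RLE gave 9 higher, the upper quartile 3 and 58, no filter 235 and 392, the CPM filter 8 higher, DESeq2 437 and 342, voom with quality weights 1716 and 2112, all 11 libraries in one fit 1 and 42, leaving out mitochondrial, rRNA and haemoglobin genes 2 and 48, and protein-coding genes 26 higher. Without chordoma 11 and 98 the counts were 60 and 163, without chordoma 10 and notochord 1 they were 0 and 0, without chordoma 11 and 98 and notochord 1 they were 397 and 740, and without chordoma 10 as well 608 and 1045. Summing chordoma 3 and 4 gave 0 and 0, and the covariate for reads outside genes 34 higher. Leaving out 1 library gave 0 to 22 higher and 0 to 102 lower. Upper-quartile factors moved the median of all genes from 0.12 to 0.00211 (log2).

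The replicate block, numbers 1 and 3 being shared by chordoma and notochord, gave 21 higher and 63 lower, with 42 of the 116 genes still past the threshold. For notochord against the controls the block gave 33 and 4. Same-numbered libraries deviated from their group means with correlations across genes of 0.294 and 0.0483 (chordoma and notochord) and -0.0185 and 0.011 (notochord and controls), against -0.175 and -0.124 for chordoma and notochord libraries of different numbers. The labels give the same-numbered libraries nothing else in common, so a pairing is neither shown nor excluded. No paired analysis was possible for chordoma against the controls because they share 1 number.

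Against 25 lists, camera with an estimated correlation gave 0 and fry 12, and leaving out 1 library gave 21 to 29. Against 0 and 0 for chordoma and the controls, no filter gave 197 and 647, DESeq2 493 and 299, and all libraries in one fit 18 and 84, with 0 to 25 and 0 to 256 when 1 library was left out. Against 0 and 0 for notochord and the controls, no filter gave 246 and 441, DESeq2 524 and 385, and all libraries in one fit 1 higher, with 0 to 0 in both directions when 1 library was left out. The overlap was 1 with all libraries in one fit. Where 1 control was left out, the lone control was assumed to vary like the tissue libraries. The stranded-column alternative was not run, because the files hold 1 count column. Depth set a floor of 0.581 to 1.58 CPM per library (3 counts, before TMM scaling). In simulated data 4-fold changes were recovered for 1.49% of genes at the spread of these libraries and for 98.5% at a dispersion of 0.1, so the spread limited small changes.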

Other observations

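Chordoma 3 and 4 stood apart from the other 4 chordomas in immune genes. The median log2 CPM of MHC class II genes was 7.72 and 8.24 in these 2 libraries against 3.26 to 4.48 in the other chordomas and 2.28 to 3.60 in notochord. Interferon-stimulated genes were at 6.30 and 6.44 against 2.47 to 4.41 and 1.17 to 1.79, macrophage genes at 6.20 and 6.001 against 2.18 to 3.93 and 1.17 to 3.70, and checkpoint genes at 4.84 and 5.09 against 1.15 to 3.16 and 0.73 to 1.03. These are values of single libraries, picked out after they were seen, and no test was made of the split.

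CPM values here are TMM-scaled over all 11 libraries. The transcripts of WWP2, a ubiquitin ligase gene expressed in cartilage, were at 119713 CPM in notochord 1, 1535 and 2131 CPM in notochord 2 and 3, 556 to 2548 CPM in the 6 chordomas, and 18.3 and 27.1 CPM in the controls. Unscaled, WWP2 held 148220 of the 3151873 gene counts in notochord 1. The median log2 CPM over 10 hepatocyte genes was 5.46 in notochord 1, against 6.53 in control 1 and at most 2.03 in the other tissue libraries. ALB was at 108 CPM in notochord 1 and at or below 5.15 CPM in the other tissue libraries, against 266 CPM in control 1. APOB, another liver gene, did not follow, at 2.42 CPM in notochord 1, 28.8 CPM in chordoma 11, 4.47 CPM in chordoma 98 and 1147 CPM in control 1. FN1, fibronectin, was at 50140 CPM in chordoma 11 and 32242 CPM in chordoma 1, and at 6088 to 9900 CPM in the other 4 chordomas. These genes were chosen after their values were seen.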
